A study of Arabidopsis thaliana with 38 samples.

How the data were processed

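RNA of 5-day seedling roots of Arabidopsis thaliana was measured on 38 ATH1 arrays in 13 groups: 30 arrays of cells sorted by the ground tissue marker J0571 (24 labelled by a one-cycle and 6 by a two-cycle protocol, per the labels), 5 arrays of dissected meristems and 3 of cells sorted by the cortex marker CO2, also of the meristematic zone per the titles. Per the labels' protocols, total RNA was extracted with a Qiagen kit for small samples and biotin was the label. The deposited values are linear intensity values of 1 colour, made by the authors with MAS5 per the submitters' processing notes, and each array has a 2% trimmed mean near the same target. The MAS5 version is not given in the sources used here. Groups and replicate numbers come from the labels. The labels call the arrays biological replicates without saying that they came from separate plants or days, so p-values measure only the spread between these samples. They do not say whether SHR and BLJ stand for mutants, and the names are used as given.

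Of 22810 probe sets, 64 controls were left out and 22746 used. The probe annotation lists 14016 of them, 13513 with 1 gene and 503 with several, and 8730 are unnamed here. No gene was named from a probe set with several. Of those with 1 gene, 13436 were matched by locus to the TAIR10.1 gene table, which was used only for names and for the order of genes. No coordinates are given. Probe sets of SHR, SCR, MGP, NUC and IME were among the unnamed.

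Changes were tested with limma 3.58.1 (lmFit and eBayes with a trend) in R 4.3.3 with the data.table package (1.17.8), on log2(intensity + 16). This scale understates the change of low signals. The values were kept as deposited, with quantile normalization between arrays where the median log2 values of the arrays of a fit spanned more than 0.5, which was so in meristem BLJ against WT. Probe sets were kept that lay above the 40th percentile of all values of the fit in at least as many arrays as the smaller of the compared groups holds. WT against SHR of the one-cycle set and the UAS lines were fitted together on 24 arrays, which share 1 estimate of the spread, and the other comparisons on their own arrays. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05, and counts at 2-fold or more are given too. The 12 comparisons are WT against SHR under each protocol, the difference between these, each of 6 UAS lines against SHR, BLJ against WT meristems, and CO2 cells against J0571 cells and against meristems. Each line was also set against WT and the lines against each other (15 pairs and an F test). The number of arrays limits the precision.

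Gene lists (17, with at least 3 measured members needed) were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, with an estimated correlation and with fry beside it. The lists of the endodermis and Casparian strip, cortex, auxin response, gibberellin, wound and stress, and the BIRD family reached 3 members somewhere, in 53 tests with 14 calls. The other lists had too few nameable members for a test. The driven gene was left out of lists in its own line. Counts of called members are given over all probe sets and adjusted over the list alone. None of the 14 calls held with an estimated correlation in the same comparison, and fry called 26 of the 53 tests. In the Results, a set is said to be called or not by camera unless fry is named. Lists of mitosis, DNA replication and histones, vascular genes, epidermis and root hairs, and endoplasmic reticulum bodies were added after the annotation was seen but before groups were compared. The list of plastid-encoded genes was added after such genes had been seen among those raised in UAS-MGP, and gene families of at least 8 tested members after a first look at the results.

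Genes were named by a rule. It takes the genes of the labels in every group, and for each list described up to 4 called members of smallest adjusted p, or, with under 2 called, the 2 of largest change as values. It also takes the 6 highest and 6 lowest changes in WT against SHR (one-cycle), in meristems and in CO2 against J0571 cells, and the 3 highest and 3 lowest in each UAS line. These had to be called with at least 2-fold change, to have exactly 1 gene, a probe set of no shared type and a mean in the higher group above the median of the tested probe sets. For WT against SHR they also had to pass in the same direction in the two-cycle arrays. A gene with several probe sets is represented by that of highest mean. Members of added lists, genes given within a profile, LBD16 in UAS-SCR and CO2 in CO2 cells fall outside the rule and were chosen after their values were seen.

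The signature score of an array is the mean of probe sets higher in WT minus the mean of those lower in WT, set to 0 at the mean of SHR. Of the driven genes, those with a named probe set (BLJ and JKD) were left out. The unnamed probe sets of SCR, MGP, NUC and IME could not be, and may remain in a signature. Groups were compared by exact permutation tests. Correlations of changes against shared SHR arrays were set beside simulated unchanged groups. Control probes (spike-ins bioB and cre, and GAPDH 3' and 5') were read as array quality. Arrays fall into profiles by the spike-ins, which set apart the line labelled UAS-JKD, UAS-SCR and meristem BLJ, and by the 10th percentile of the signal, which sets apart the UAS lines other than UAS-BLJ. UAS-NUC, UAS-MGP and UAS-IME, whose spike-ins resemble those of SHR, were also compared with each other, as were UAS-SCR and the line labelled UAS-JKD. WT, SHR and UAS-BLJ of the one-cycle set share these values, though WT differs from SHR in the actin ratio. The GAPDH ratios of the UAS lines other than UAS-BLJ also lie above those of SHR. For the other lines against SHR and for meristems, a batch seen in these values and the group cannot be told apart.

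Replicate numbers were checked for pairing by the correlation of deviations from the group means, reading 2_x in the SHR labels as x, which the labels do not state. They pair only UAS-IME and SHR (r from 0.182 to 0.543, all above 0.1), and the fit with the number as a block over all 24 arrays called 3320 probe sets there against 3333. That block is common to all groups of the fit and need not remove a pairing of UAS-IME and SHR. No paired fit of these 2 groups alone was made. No duplicate arrays were found. The test was tested on simulated data with 200 changed probe sets: 63% of 2-fold and 97% of 4-fold changes were recovered in WT against SHR one-cycle, 7% and 54% in the two-cycle set, 24% and 81% in CO2 against J0571 cells, 0% and 46% in CO2 cells against meristems, and 0% of either in meristem BLJ against WT. With so few changed probe sets the adjusted threshold is stricter than in data with many calls. In the data, CO2 cells against meristems gave 11113 calls, 8864 of them by at least 2-fold. The recovered shares therefore hold for such sparse changes only and do not give the power in these data. Alternatives were other scaling, pseudocounts of 1 and 64, no filter or a 70th percentile filter, eBayes without trend, the arrays of the 2 groups alone, replicate blocks and leaving out each array. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.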

Results

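The data were RNA levels in roots of 5-day Arabidopsis thaliana seedlings, read on 38 single-colour ATH1 arrays, each hybridised with biotin-labelled RNA of 1 sample. Of these, 30 arrays (10 groups of 3) came from cells sorted by J0571, a marker of the ground tissue, the root layers that hold the cortex and the endodermis, in the C24 ecotype. Wild type (WT) and a line labelled SHR were each labelled by a two-cycle protocol (6 arrays) and by a one-cycle protocol. In the one-cycle set, 6 further lines carried UAS-BLJ, UAS-NUC, UAS-MGP, UAS-JKD, UAS-SCR or UAS-IME in the SHR background. The remaining arrays, of the Columbia ecotype, came from meristems labelled WT (2 arrays) or BLJ (3 arrays) and from cells sorted by the cortex marker CO2 (3 arrays). The titles place both in the meristematic zone and name no zone for the J0571 arrays. SHR and SCR are transcription factors of root radial patterning, and the BIRD genes BLJ, JKD, MGP, NUC and IME encode zinc finger proteins that act with them. The median signal of an array ran from 55.8 to 177.5, and the precision of every value below is limited by the number of arrays, 3 per group except for the 2 meristem WT arrays. Changes are on the log2(signal + 16) scale with their standard error (SE), signals are group means ± SD, and gene names are those of the probe annotation. Genes called highest or lowest are so only among the probe sets that the rule for named genes admits, and others, named or unnamed, changed more in some comparisons.

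The genes named in the labels came first. BLJ had a signal of 195.8 ± 26.1 (n = 3) in WT and 14.2 ± 9.1 (n = 3) in SHR of the one-cycle set, a log2 difference of 2.85 ± 0.39 (SE, adjusted p = 9.29e-06), and in the two-cycle set 105.9 ± 90.4 against 8.0 ± 4.7. In UAS-BLJ the signal was 443.3 ± 40.1, above SHR by 3.97 ± 0.39 on the log2 scale (adjusted p = 3.97e-07), and in the other 5 lines it lay between 5.6 and 29.8. In meristems the BLJ probe was close to the floor in both groups (5.2 ± 6.1 in WT and 10.3 ± 7.1 in BLJ), so it gives no check of that label. JKD went against 1 label. Its signal was 215.1 ± 41.2 in SHR, 147.4 ± 23.4 in WT and 102 ± 15.4 in the arrays labelled UAS-JKD, a fall of the log2 value against SHR (-0.96 ± 0.22, adjusted p = 0.00169). If the probe lies outside the part of JKD that the transgene carries, it checks nothing, and the group is called the line labelled UAS-JKD throughout. Between WT and SHR the change was -0.495 (adjusted p = 0.0848, but 0.0468 on the 6 arrays alone). JKD also fell in UAS-BLJ (-2.33), UAS-IME (-2.55) and UAS-NUC (-1.50). In UAS-MGP it fell by 0.75 (adjusted p = 0.0345), a call that ended without SHR 2_1 (adjusted p = 0.0877), SHR 2_3 (0.148), or UAS-MGP 1 (0.0924), 2 (0.108) or 3 (0.051). No probe set that could be named belonged to SHR, SCR, MGP, NUC or IME, so those labels were not checked.

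**Figure D1:**
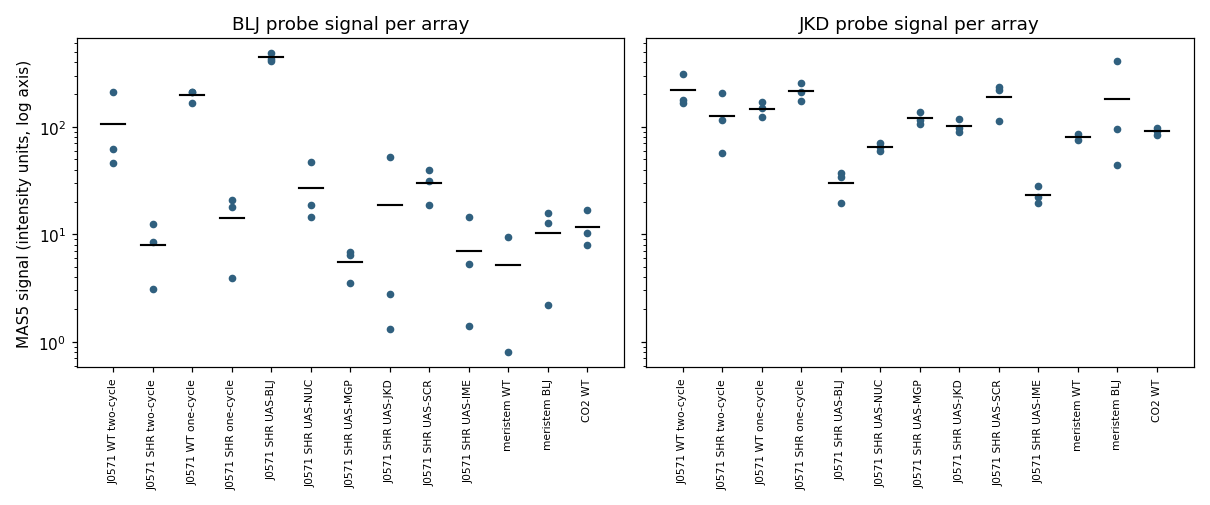
Signal of the BLJ probe (left) and the JKD probe (right) on each array (points) with the group mean (bar), in MAS5 intensity units on a log axis, for the 13 groups. BLJ stands at 443.3 on average in UAS-BLJ against 14.2 in SHR one-cycle, and JKD at 102 in the arrays labelled UAS-JKD against 215.1 in SHR one-cycle.

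The first comparison asks how ground tissue cells of the SHR line differ from those of WT. Highest in WT of the one-cycle set was the peroxidase gene AT4G11290, which read 5087 ± 585 in WT and 31.6 ± 7.53 in SHR (log2 change 6.75 ± 0.26, adjusted p = 6.03e-14), and a further peroxidase gene, AT1G44970, was higher by 4.22 ± 0.36. AT5G45210 (5.83 ± 0.22), AT2G14900 of the gibberellin-regulated family (5.48 ± 0.23), AT3G22620 (3.79 ± 0.35) and AT2G22620 (3.78 ± 0.46) completed the 6 highest genes of the rule. Lowest in WT was AT2G25450, a dioxygenase of glucosinolate side chain modification, at 11.3 ± 7.12 against 1605 ± 401 in SHR (-5.89 ± 0.32, adjusted p = 2.14e-11). It was followed by AT2G40010 (-4.54), the peroxidase gene AT5G64120 (-4.25), AT4G20480 (-4.07), GH3.3, which encodes an auxin-conjugating enzyme (-3.72, 120.7 ± 23.2 against 1803 ± 437), and AT4G15390 (-3.71). These 12 genes were required to pass in the same direction in the two-cycle set too, where AT4G11290 was higher by 7.43 and AT2G25450 lower (-5.26). With limma, 5445 of 15777 probe sets were called, 2682 higher and 2763 lower in WT (2618 and 2390 after quantile normalization), and 2021 of them by at least 2-fold. The actin control probes at the 3' end stood above those at the 5' end by -0.35 ± 0.59 (SD, log2) in WT and 0.94 ± 0.03 in SHR. In arrays of the Columbia ecotype, AT4G20480 had a mean signal of 530.3 in CO2 cells and 796.4 in WT meristems, AT2G40010 177.6 and 645.9, AT2G25450 6025 and 116.7, and AT5G45210 7.07 and 230.7.

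Genes of the endodermis and its Casparian strip, the wall barrier of that layer, were higher in WT. Of 4 measured members, 3 rose and 1 fell in the one-cycle set, and the same counts held when adjusted over the list alone. DIR9, a dirigent protein gene, read 2688 ± 616 in WT and 309.2 ± 68.6 in SHR (3.05 ± 0.32, adjusted p = 3.02e-07), and the receptor kinase genes SGN1 and GSO1 were higher by 3.04 ± 0.34 and 2.25 ± 0.28. EN7 fell (-0.90 ± 0.26, adjusted p = 0.0105), a call that ended without WT 2_1 (adjusted p = 0.0643) or SHR 2_3 (0.0528). The list moved up as a set (camera, adjusted p = 0.0166, and adjusted p = 0.13 with an estimated correlation). Of the 5 cortex genes measured, AT1G62510 (-4.73 ± 0.27) and CO2 (-2.54 ± 0.44) fell in WT and AT5G02000 rose (1.10 ± 0.21), the same counts adjusted over the list alone. The set was not called by camera (adjusted p = 0.187) but was by fry (adjusted p = 4.2e-07). Among 6 auxin response genes, GH3.3, WES1 (-1.70) and IAA29 (-1.27) fell, and the set test missed the threshold by camera (adjusted p = 0.0565) and passed by fry (adjusted p = 0.00124). GID1B, a gibberellin receptor gene, rose (0.93, 1 of 3 gibberellin genes, adjusted p = 0.932, median -0.22 but mean 0.16), as did CML38, a calmodulin-like gene (1.68, 1 of 3 wound and stress genes, adjusted p = 0.484).

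In the two-cycle set all 4 endodermis genes rose in WT, also when adjusted over the list alone. DIR9 was higher by 5.01 ± 0.50, SGN1 by 4.30 ± 0.62 and GSO1 by 2.86 ± 0.59. EN7 rose by 1.31 ± 0.36 (adjusted p = 0.031), the opposite of its one-cycle direction, but its call ended without WT 1 (adjusted p = 0.0989), WT 2 (0.0513), WT 3 (0.0938) or SHR 2 (0.0534) and with the replicate number as a block (0.0555). The set moved up (adjusted p = 0.00582, and adjusted p = 0.191 with an estimated correlation). Cortex genes gave no set test, and CO2 (1.75 ± 1.07, adjusted p = 0.244) and CORTEX (-0.40 ± 0.38, adjusted p = 0.445) are given as values. Auxin (1 up and 1 down of 4, adjusted p = 0.859) and wound genes (1 down of 3, adjusted p = 0.859) were not called, and in both the median (0.22 and 0.35) and the mean (-0.77 and -0.20) had opposite signs. Of 14331 probe sets tested, 4122 were called, 2125 higher and 1997 lower in WT, a balance that turned to 1932 and 2213 after quantile normalization. The count was 2058 without WT 1, 2202 without WT 3, 2378 without SHR 2 and 2657 with the replicate number as a block.

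The difference between WT and SHR depended on the labelling set. The interaction term was called for 5697 of 15584 probe sets (3210 positive, 2487 negative), with the two-cycle difference taken minus the one-cycle difference. After quantile normalization 2694 were positive and 2776 negative. Across 13929 probe sets tested in both, which are not independent replicates, the log2 changes correlated at r = 0.14. Of 1440 probe sets called in both, 968 went the same way (453 higher in WT, where independent lists would share 364, and 515 lower, against 350) and 472 went opposite ways. The control probes of the arrays differed as well. The GAPDH control probes at the 3' end stood above those at the 5' end by 2.46 ± 0.57 (SD, log2) on the two-cycle SHR arrays, by -0.02 ± 0.11 on the two-cycle WT arrays and by -0.05 ± 0.16 on the one-cycle SHR arrays. For actin the ratio was 2.73 ± 0.41 on the two-cycle SHR and -2.44 ± 0.13 on the two-cycle WT arrays. In the one-cycle set it was 0.94 ± 0.03 in SHR and -0.35 ± 0.59 in WT.

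The UAS lines ask what each gene does to SHR ground tissue. In UAS-BLJ, the driven gene itself gave the highest change among the probe sets of the rule (an unnamed one reached 5.465), followed by UGT72E3, a glycosyltransferase gene (3.76 ± 0.17, 1013 ± 104 against 59.9 ± 5.92 in SHR, adjusted p = 7.02e-12), and AT4G16980 (3.75 ± 0.21). AT1G10390 (-3.34 ± 0.34), AT4G22460 (-2.81 ± 0.26) and TBL36 (-2.70 ± 0.41) were lowest. Cortex genes went both ways, 2 up and 2 down of 5, also over the list alone: CORTEX rose (2.73 ± 0.25, 5316 ± 407 against 801.4 ± 199), CO2 (-2.62 ± 0.44) and AT1G62510 (-2.57 ± 0.27) fell, and the set did not shift (adjusted p = 0.534). NPF6.4 was called at the edge (0.51, adjusted p = 0.0498) and lost without SHR 2_2 (adjusted p = 0.254), SHR 2_3 (0.144), or UAS-BLJ 1 (0.0687), 2 (0.113) or 3 (0.2). DIR9 fell (-1.43 ± 0.32), the 1 called of 4 endodermis genes (2 adjusted over the list alone, adjusted p = 0.143 for the set), and SGN1 read -0.91 ± 0.34 (adjusted p = 0.0891, but 0.000829 on the 6 arrays of UAS-BLJ and SHR alone). WRKY53 rose (1.49 ± 0.33), the 1 called of 3 wound genes (adjusted p = 0.143), while no auxin (adjusted p = 0.388) or gibberellin (adjusted p = 0.629) gene was called. In all 1756 probe sets were called (1020 up, 736 down), 829 of them by at least 2-fold. Fitted on the 6 arrays of UAS-BLJ and SHR alone, the count was 3456. Control probes of these arrays resembled those of SHR, with a spike-in ratio of -5.33 against -5.35 (log2 bioB over cre).

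In UAS-NUC, AT5G25450 was highest against SHR (3.67 ± 0.29, 1254 ± 400 against 80.0 ± 5.75, adjusted p = 2.53e-08), then AT1G52560 (3.498 ± 0.465) and AT5G41810 (3.33 ± 0.39). AT4G20480 (-3.53 ± 0.21), AT1G23960 (-3.36 ± 0.22) and the cortex gene AT1G62510 (-3.35 ± 0.27) were lowest among the probe sets of the rule, while 2 unnamed ones reached -5.487 and -4.552. CO2 fell too (-2.34 ± 0.44) and NPF6.4 rose (0.81 ± 0.16), so that 1 cortex gene rose and 2 fell of 5, over the list alone as well (adjusted p = 0.52). GSO1 rose (1.37 ± 0.28) and EN7 fell (-1.34 ± 0.26) of the 4 endodermis genes (adjusted p = 0.856). CML38 (1.68 ± 0.30) and WRKY53 (0.93 ± 0.33) rose of 3 wound genes (adjusted p = 0.178), GID1A fell (-0.68 ± 0.14) of 3 gibberellin genes (adjusted p = 0.856, median 0.08 and mean 0.02 but the test pointing down) and no auxin gene was called (adjusted p = 0.575). Markers of the epidermis and root hairs, layers outside the sorted tissue, moved up as a set (3 of 6 rose, adjusted p = 0.0221, and adjusted p = 0.505 with an estimated correlation), also against UAS-MGP and UAS-IME (3 of 6, adjusted p = 0.00217, and adjusted p = 0.169 with an estimated correlation). Calls numbered 6423 (3172 up, 3251 down), but 3496 without UAS-NUC 1, 4150 without UAS-NUC 3 and 3494 on the 6 arrays alone. The low end of the signal differed from SHR, with a 10th percentile of 8.30 to 9.83 per array against 3.23 to 3.43. The 3' to 5' ratio was 0.705 ± 0.051 (SD, log2) for GAPDH, against -0.05 ± 0.16 in SHR. For actin it was 1.64 ± 0.23 against 0.94 ± 0.03. Against UAS-MGP and UAS-IME, whose arrays share that low end, 2798 of 15777 probe sets were called, and 32.4% of the calls against SHR passed again in the same direction and 30 in the opposite one. Both contrasts use the same UAS-NUC arrays, so part of this share is built in, and no share by chance was computed. AT4G20480 stayed lower there (-3.43 ± 0.18) and AT5G25450 higher (2.26 ± 0.25), whereas AT1G62510 read -0.13 ± 0.23 (adjusted p = 0.7).

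In UAS-MGP, AT5G15360 (3.07 ± 0.24, 304.1 ± 132 against 20.4 ± 3.43), the TIR-type resistance gene CSA1 (2.42 ± 0.15) and the photosystem I gene psaI (2.14 ± 0.27) were highest, and AT5G23830 (-3.37 ± 0.21, 174.1 ± 5.83 against 1954 ± 188) and AT1G10390 (-2.63 ± 0.34) lowest. AT1G52070 (-2.55 ± 0.65, adjusted p = 0.0167) was the next, lost without SHR 2_2 (adjusted p = 0.0618) or UAS-MGP 1 (0.0803). Endodermis genes fell as a set (adjusted p = 0.0392, and adjusted p = 0.21 with an estimated correlation), with 2 of 4 called and 3 adjusted over the list alone. They were DIR9 (-1.56 ± 0.32) and SGN1 (-1.36 ± 0.34, adjusted p = 0.0144, but 0.0564 without SHR 2_1, 0.0755 without UAS-MGP 1 and 0.0517 without UAS-MGP 3). The set call ended without SHR 2_1 (adjusted p = 0.13) or UAS-MGP 1 (0.141). Auxin response genes also fell as a set (adjusted p = 0.0392, and adjusted p = 0.312 with an estimated correlation and 0.116 with fry), with LBD16 the 1 called of 6, over the list alone too. Its change was -1.08 ± 0.32 (adjusted p = 0.0365, but 0.139 without SHR 2_1, 0.0872 without SHR 2_2, 0.129 without UAS-MGP 1, 0.0957 without UAS-MGP 3 and 0.0815 with a pseudocount of 64), and GH3.3 read -0.90 ± 0.37 (adjusted p = 0.136, and 0.0423 without UAS-MGP 2). The auxin set call ended without SHR 2_1 (adjusted p = 0.146), UAS-MGP 1 (0.217) or UAS-MGP 3 (0.106). Of 5 cortex genes AT1G62510 fell (-1.96 ± 0.27) and CORTEX rose (1.43 ± 0.25, adjusted p = 0.591 for the set). Gibberellin (1 of 3 fell, adjusted p = 0.147) and wound genes (adjusted p = 0.847, median 0.03 and mean 0.04 but the test pointing down) were not called as sets, and none of the 3 wound genes passed. Calls numbered 1431 (837 up, 594 down, and 625 up and 615 down after quantile normalization), and 808, 854 and 821 without SHR 2_1, 2_2 and 2_3, 790 without UAS-MGP 1 and 819 without UAS-MGP 3. The 10th percentile of the arrays was 8.08 to 8.74. The GAPDH 3' to 5' ratio was 0.91 ± 0.25 against -0.05 ± 0.16 in SHR. The actin ratio of UAS-MGP 2 was -0.771 against 1.311 and 1.258 on the others. Against UAS-NUC and UAS-IME, 3631 of 15777 probe sets were called, and of the calls against SHR 24% passed again in the same direction and 80 in the opposite one. Both contrasts use the same UAS-MGP arrays, so part of this share is built in, and no share by chance was computed. AT5G23830 (-2.525 ± 0.18) and AT1G10390 (-3.33 ± 0.30) stayed lower against these lines. The 3 highest genes changed less there: AT5G15360 by 0.71 ± 0.21, CSA1 by 0.48 ± 0.13 and psaI by 0.14 ± 0.23 (adjusted p = 0.669). AT1G52070 read -0.68 ± 0.56 (adjusted p = 0.365). The endodermis genes (SGN1 -2.32 ± 0.29, DIR9 -1.51 ± 0.27, set adjusted p = 0.00996, and adjusted p = 0.0855 with an estimated correlation) and auxin genes (GH3.3 -1.43 ± 0.32, set adjusted p = 0.00996, and adjusted p = 0.186 with an estimated correlation) were lower there too. The cortex set was higher there (3 of 5, adjusted p = 0.00996, and adjusted p = 0.0765 with an estimated correlation) and the wound set lower (3 of 3, adjusted p = 0.00996, and adjusted p = 0.133 with an estimated correlation), neither of which was called against SHR. Of the cortex genes, AT1G62510 fell against SHR in all 3 lines and only fell less here (-1.96, against -3.35 in UAS-NUC and -4.48 in UAS-IME). These differences mirror those of UAS-NUC and UAS-IME and add no separate evidence. Epidermis and root hair markers were lower there (4 of 6 fell, adjusted p = 0.00366, and adjusted p = 0.228 with an estimated correlation).

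In the line labelled UAS-JKD, AT3G28550 read 1934 ± 966 against 57.9 ± 45.9 in SHR (4.76 ± 0.69, adjusted p = 3.84e-05), with AT2G45750 (4.14 ± 0.53) and the glutathione S-transferase gene GSTU28 (3.995 ± 0.526) next. AT2G25450 (-5.25 ± 0.32, 26.3 ± 8.42 against 1605 ± 401), AT2G43535 (-3.70 ± 0.27) and AT2G40010 (-3.503 ± 0.302) were lowest. CO2 fell (-1.91 ± 0.44) and AT5G02000 rose (0.75 ± 0.21) among 5 cortex genes (2 up and 1 down, 3 up and 1 down adjusted over the list alone, adjusted p = 0.736, median 0.42 but mean -0.07). NPF6.4 (0.42, adjusted p = 0.0414) was lost without SHR 2_2 (adjusted p = 0.204), SHR 2_3 (0.107), UAS-JKD 2 (0.0802) or UAS-JKD 3 (0.167) and on the 6 arrays alone (0.0895). EN7 fell (-1.27 ± 0.26) and GSO1 rose (1.08 ± 0.28) of the endodermis genes (adjusted p = 0.648), and DIR9 (-0.96 ± 0.32, adjusted p = 0.018) was lost without SHR 2_1 (adjusted p = 0.0679) or UAS-JKD 2 (0.103). WES1 (0.98), LBD29 (1.23) and IAA30 (0.97) rose of 6 auxin genes (adjusted p = 0.55) and WRKY53 (1.04) and CML38 (0.90) of 3 wound genes (adjusted p = 0.585), with no gibberellin gene called (adjusted p = 0.794, median -0.09 but mean 0.01). Calls numbered 7287 (3697 up, 3590 down, a balance that turned to 3409 and 3686 after quantile normalization), 2704 of at least 2-fold. Markers of the epidermis and root hairs, layers outside the sorted tissue, were higher in these arrays: all 6 measured rose, among them GH9C1 (3.29 ± 0.37), EXPA7 (2.86 ± 0.46), EXPA18 (2.14 ± 0.35) and CSLD2 (1.68 ± 0.24), and the set moved up (adjusted p = 0.000231, and adjusted p = 0.484 with an estimated correlation). The spike-in ratio was -7.66 against -5.35 in SHR and the GAPDH 3' to 5' ratio 1.22 against -0.05.

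In UAS-SCR, AT3G28550 (4.12 ± 0.69) and AT2G45750 (3.55 ± 0.53) were again among the highest, beside AT5G03350 (3.81 ± 0.36, 591.8 ± 153 against 29.7 ± 19.9). AT2G25450 (-5.26 ± 0.32), AT5G62210 (-4.40 ± 0.37) and CHIL, a chalcone isomerase-like gene (-3.53 ± 0.27, 249.9 ± 118 against 2860 ± 462), were lowest. Auxin response genes rose together, 5 of 6 also adjusted over the list alone: LBD29 (2.24 ± 0.38) and LBD16 (1.46 ± 0.32), which act in lateral root formation, the auxin conjugating GH3.3 (2.11 ± 0.37, 8446 ± 4830 against 1803 ± 437) and WES1 (1.61 ± 0.29), and IAA30 (1.68 ± 0.34). The set moved up (adjusted p = 0.00437, and adjusted p = 0.378 with an estimated correlation). SGN1 (2.02 ± 0.34) and GSO1 (1.37 ± 0.28) rose and EN7 (-1.30 ± 0.26) fell of the endodermis genes (3 up and 1 down, adjusted p = 0.373). DIR9 (0.87, adjusted p = 0.0291) was lost without SHR 2_2 (adjusted p = 0.122), SHR 2_3 (0.0591), UAS-SCR 1 (0.107) or UAS-SCR 3 (0.093). CO2 fell (-2.32 ± 0.44) and AT1G62510 (0.91, adjusted p = 0.00936) rose among cortex genes (adjusted p = 0.541, median 0.35 but mean -0.05), the latter lost without UAS-SCR 3 (adjusted p = 0.0681). GID1B (1.38) and CML38 (1.13) rose, each 1 of 3 (gibberellin adjusted p = 0.484, wound adjusted p = 0.373). Calls numbered 7524 (3955 up, 3569 down, a balance that turned to 3389 and 3811 after quantile normalization), and 4503 without UAS-SCR 3. Epidermis and root hair markers were higher here too (5 of 6, GH9C1 2.85 ± 0.37 and EXPA7 2.21 ± 0.46, adjusted p = 0.00616, and adjusted p = 0.47 with an estimated correlation), with a spike-in ratio of -7.85 and a GAPDH ratio of 1.399. Between UAS-SCR and the line labelled UAS-JKD, whose arrays share these values, 368 of 15777 probe sets were called. SGN1 (2.33 ± 0.34), DIR9 (1.83 ± 0.32) and GH3.3 (2.06 ± 0.37) were higher in UAS-SCR, and so were the endodermis set (adjusted p = 0.00108, and adjusted p = 0.0483 with an estimated correlation) and the auxin set (adjusted p = 7e-04, and adjusted p = 0.1 with an estimated correlation). Epidermis and root hair markers were lower in UAS-SCR (1 of 6 fell, adjusted p = 0.0292, and adjusted p = 0.312 with an estimated correlation). AT2G25450 differed by -0.01 ± 0.32, and 2.5% of either line's calls against SHR passed again in the same direction, with 22 of UAS-SCR and 24 of the line labelled UAS-JKD passing in the opposite direction. A change that both lines share would not pass here whatever its cause, so this low share does not tell a batch from a shared effect.

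In UAS-IME, AT1G51990 (4.12 ± 0.27, 324 ± 66 against 3.53 ± 2.87), AT3G29410 (3.60 ± 0.32, 3299 ± 156 against 274 ± 128) and AT2G43620 (3.41 ± 0.38) were highest. The cortex genes AT1G62510 (-4.48 ± 0.27, 36.7 ± 15 against 1145 ± 246) and CO2 (-3.26 ± 0.44) and a further gene, AT1G62480 (-3.38 ± 0.23), were lowest. The cortex list fell as a set (adjusted p = 0.0235, and adjusted p = 0.054 with an estimated correlation), with 1 of 5 up, CORTEX (1.48 ± 0.25), and 2 down, or 4 down adjusted over the list alone. GSO1 (1.70 ± 0.28) and SGN1 (1.32 ± 0.34) rose and EN7 (-1.10 ± 0.26) fell of 4 endodermis genes (adjusted p = 0.51). Wound genes moved up (adjusted p = 0.0478, and adjusted p = 0.4 with an estimated correlation) with WRKY53 (1.95 ± 0.33) called and 2 called over the list alone. CML38 read 0.83 ± 0.30 (adjusted p = 0.0537, but 0.0409 without UAS-IME 2 and 0.022 on the 6 arrays alone), and the set call ended without SHR 2_2 (adjusted p = 0.123), UAS-IME 1 (0.0712) or UAS-IME 3 (0.0564). Auxin (adjusted p = 0.917, median 0.07 and mean 0.04 but the test pointing down) and gibberellin genes (adjusted p = 0.917) held no called member. Calls numbered 3333 (2081 up, 1252 down, and 1745 up and 1437 down after quantile normalization), 1896 without UAS-IME 1 and 2102 without SHR 2_2. The 10th percentile of these arrays was 8.31 to 9.53. The GAPDH 3' to 5' ratio was 0.51 ± 0.18 against -0.05 ± 0.16 in SHR, and the actin ratio 1.64 ± 0.10 against 0.94 ± 0.03. Against UAS-NUC and UAS-MGP, 1221 of 15777 probe sets were called, and of the calls against SHR 22.3% passed again in the same direction and 27 in the opposite one. Both contrasts use the same UAS-IME arrays, so part of this share is built in, and no share by chance was computed. There the cortex set stayed lower (AT1G62510 -1.83 ± 0.23, CO2 -1.66 ± 0.38, adjusted p = 0.00099, and adjusted p = 0.00795 with an estimated correlation) and the endodermis set was higher (SGN1 1.70 ± 0.29, adjusted p = 0.0049, and adjusted p = 0.0498 with an estimated correlation). Part of the endodermis difference comes from UAS-MGP, in which SGN1 and DIR9 fell against SHR. Against SHR the endodermis set of UAS-IME was not called.

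**Figure D2:**
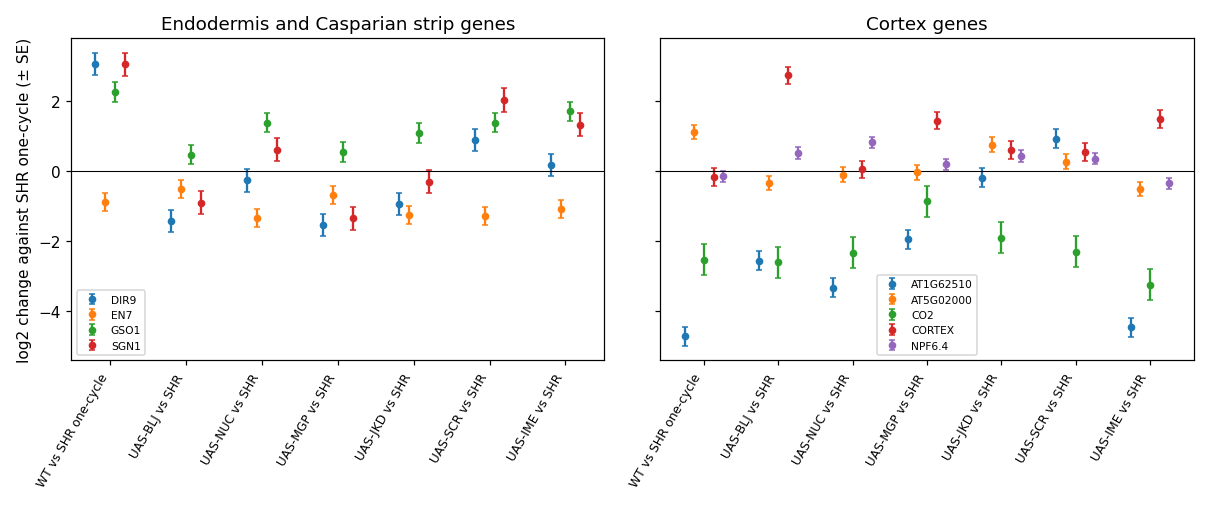
Log2 change against SHR one-cycle (± SE, 3 arrays per group) of the measured endodermis and Casparian strip genes (left) and cortex genes (right) in WT and the 6 UAS lines. DIR9 reaches 3.05 in WT and -1.56 in UAS-MGP, and AT1G62510 -4.73 in WT and -4.48 in UAS-IME.

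Set against WT, each line differed in many probe sets. SHR itself gave 5445 calls, UAS-BLJ 5528, UAS-NUC 3754, UAS-MGP 5307, the line labelled UAS-JKD 4931, UAS-SCR 5772 and UAS-IME 4345. With 1 array left out, the count of UAS-NUC ran from 2695 (without UAS-NUC 3) to 5376 (without UAS-NUC 2), and that of SHR from 3933 to 5358. Among the 6 lines, an F test called 10456 of 15777 probe sets (66.3%). Of the 15 pairs of lines, UAS-SCR and the line labelled UAS-JKD differed least (368 calls), followed by UAS-NUC and UAS-IME (1274), and UAS-SCR differed most from UAS-BLJ and UAS-MGP (6825 each). The changes against SHR correlated across probe sets, which are not independent replicates, at r = 0.89 between UAS-SCR and the line labelled UAS-JKD, 0.75 between UAS-NUC and UAS-IME and 0.65 between UAS-BLJ and UAS-IME, where unchanged groups simulated against the same SHR arrays gave 0.50. In 7 of the 15 pairs r lay below that value, from 0.293 (UAS-MGP and UAS-SCR) to 0.465 (UAS-NUC and UAS-MGP). Changes in 1 line alone add spread and lower r, so an r below that value does not show less sharing. The covariance lay above the simulated one in every pair, by 0.0402 in the lowest (UAS-BLJ and UAS-MGP). UAS-SCR and the line labelled UAS-JKD shared 2747 raised probe sets (927 from independent lists) and 2690 lowered ones (812), with 19 opposite. The covariance exceeded the simulated 0.033 by a median of 0.131 over the 15 pairs (jackknife SE 0.073), but by 0.0865 without SHR 2_2 and 0.0826 with a pseudocount of 64. With 3 SHR arrays the controls could not be split into 2 sets of at least 2 arrays, so part of the counts shared by lines may come from the shared controls.

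A signature score asked how far each line moved from SHR towards WT. The fixed signature came from the two-cycle arrays, which enter no UAS comparison, and held 1517 probe sets higher and 1575 lower in WT. WT of the one-cycle set scored 0.38 ± 0.24 (SD, n = 3, exact two-sided permutation p = 0.2) with SHR at 0. All 6 lines scored on the other side, UAS-SCR at -0.97 ± 0.43, the line labelled UAS-JKD at -0.85 ± 0.20, UAS-NUC at -0.82 ± 0.57, UAS-IME at -0.58 ± 0.30, UAS-BLJ at -0.24 ± 0.12 (-0.147 without SHR 2_2) and UAS-MGP at -0.14 ± 0.32. The score of UAS-MGP was 0.05 without UAS-MGP 2, -0.038 without SHR 2_2, -0.232 without SHR 2_1, -0.248 without UAS-MGP 1 and -0.207 without UAS-MGP 3. With 3 arrays against 3 the smallest exact p is 0.1, and adjusted over the lines the exact p-values ran from 0.2 to 0.7. The two-cycle SHR arrays had a GAPDH 3' to 5' ratio of 2.46 (log2) against -0.02 in two-cycle WT. Among the lines that ratio was 1.399 in UAS-SCR, 1.215 in the line labelled UAS-JKD, 0.705 in UAS-NUC, 0.508 in UAS-IME and 0.021 in UAS-BLJ. UAS-MGP, at 0.908, scored near SHR all the same. Whether this signature reads 3' bias was not tested. The alternative signature, taken from the one-cycle arrays (976 higher, 1044 lower), gave the opposite sign in every line. Against 3.14 ± 0.33 in WT, UAS-NUC scored 1.80 ± 0.44, the line labelled UAS-JKD 1.46 ± 0.17, UAS-SCR 1.34 ± 0.39, UAS-IME 1.10 ± 0.26, UAS-MGP 0.49 ± 0.27 and UAS-BLJ 0.41 ± 0.12 (adjusted exact p = 0.1 each, the smallest possible). The score of WT is set by the choice of the signature on these same arrays and tests nothing. The signature also shares its SHR arrays with the lines, and simulated unchanged lines scored 0.17 ± 0.01. That SD understates the spread, because the simulation drew each probe set independently. The real SHR arrays had an SD of 0.17, so the distance of a line from the simulated score cannot be read in units of that SD.

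**Figure D3:**
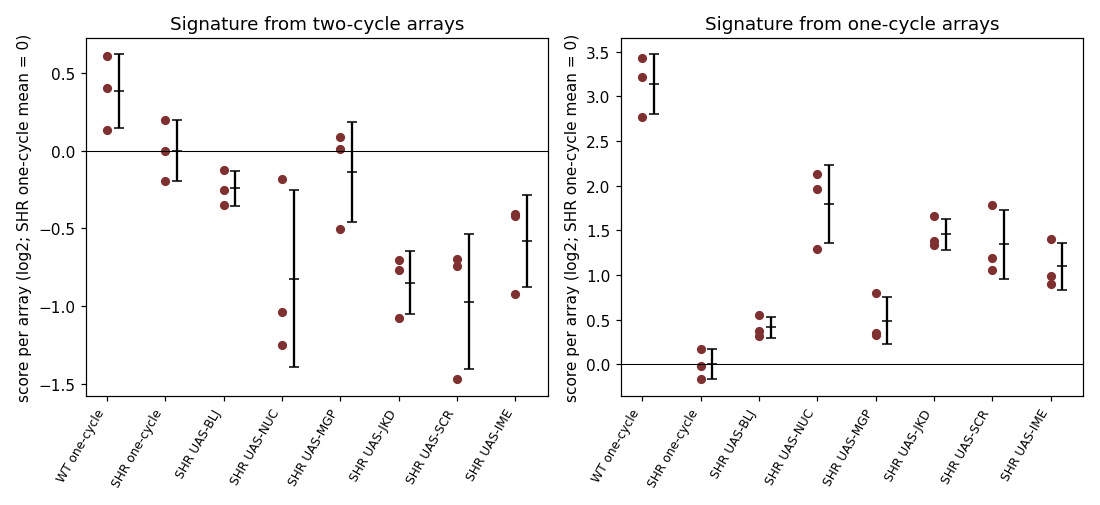
Signature score of each one-cycle array (points) with the group mean and SD, set to 0 at the mean of SHR one-cycle, in log2 units, for a signature from the two-cycle arrays (left) and from the one-cycle arrays (right). UAS-SCR averages -0.97 on the left and 1.34 on the right.

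**Figure D4:**
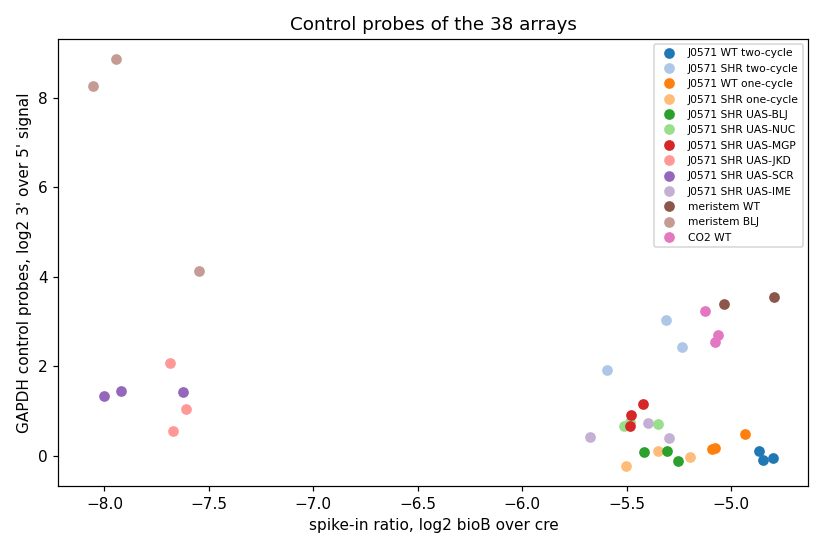
Control probes of the 38 arrays: the log2 ratio of the spike-ins bioB and cre (horizontal) and the log2 ratio of 3' to 5' GAPDH signal (vertical), 1 point per array, coloured by group. The arrays labelled UAS-JKD (-7.66 on average), UAS-SCR (-7.85) and meristem BLJ (-7.85) stand to the left of SHR one-cycle (-5.35).

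Meristems labelled BLJ were compared with WT meristems. LCR69, a defensin-like gene, read 5455 ± 1830 (n = 3) in BLJ and 7.96 ± 9.63 (n = 2) in WT (7.61 ± 0.46, adjusted p = 0.00248), and AT4G29200 (7.09 ± 0.39), AT3G28550 (5.75 ± 0.58), AT1G04040 (5.39 ± 0.43), the isocitrate lyase gene ICL (5.30 ± 0.74) and AT5G12880 (5.24 ± 0.42) followed. AT2G14460 (-6.22 ± 0.50, 28.5 ± 27.3 against 2767 ± 86), the glutathione S-transferase gene ATGSTF13 (-4.36 ± 0.39), AT5G22580 (-4.24 ± 0.48), the expansin gene EXPA4 (-3.85 ± 0.54), AT5G45210 (-3.83 ± 0.52) and the peroxidase gene Prx37 (-3.48 ± 0.48) were lowest. Cortex genes moved up as a set (adjusted p = 0.036, and adjusted p = 0.311 with an estimated correlation), with 0 of 3 called by limma and 3 adjusted over the list alone. CO2 read 1.84 ± 0.46 (adjusted p = 0.0875, but 0.0337 without BLJ 1, 0.0156 on the values as deposited and 0.00268 with the replicate number as a block) and AT5G02000 1.98 ± 0.68 (adjusted p = 0.15), and the set call ended without WT 1 (adjusted p = 0.0556) and on the values as deposited (0.0704). Endodermis (GSO1 1.82 ± 0.65, adjusted p = 0.156 but 0.0442 on the values as deposited, DIR9 1.02 ± 0.93, adjusted p = 0.509, set adjusted p = 0.389), auxin (adjusted p = 0.201) and wound genes (1 of 3 up, adjusted p = 0.201) did not shift as sets by camera. Fry called the auxin set (adjusted p = 0.0355) and the wound set (adjusted p = 0.0352). JKD read 181.6 ± 195.9 in BLJ and 81.2 ± 7.6 in WT. Limma called 423 of 15534 probe sets, 354 up (83.7%) and 69 down, all by at least 2-fold. The count was 115 without WT 1, 116 without WT 2, 2425 without BLJ 1 (1183 up, 1242 down) and 1802 without BLJ 3 (992 up, 810 down). It was 0 without BLJ 2, where 2747 had an unadjusted p under 0.05 and each of the 12 genes named first was lost (LCR69 adjusted p = 0.145). Without WT 1 the calls of ATGSTF13 (adjusted p = 0.056), AT5G22580 (0.274), EXPA4 (0.295), AT5G45210 (0.397) and Prx37 (0.235) ended, and without WT 2 the last 4 of these (0.183, 0.293, 0.51 and 0.228). A 70th percentile filter also ended the calls of AT5G22580 (adjusted p = 0.0611) and EXPA4 (0.0744), and a pseudocount of 1 that of AT5G45210 (0.0571). On the values as deposited, without quantile normalization, 2140 were called, 63.1% of them up. The BLJ arrays correlated with each other from 0.696, their GAPDH 3' to 5' ratio was 7.09 ± 2.58 against 3.48 ± 0.11 in WT, and their spike-in ratio -7.85 against -4.92. BLJ 1 lay nearer to WT, with a GAPDH ratio of 4.125 against 3.395 and 3.556 on the WT arrays and a correlation of 0.898 with WT against 0.876 with its own group. No WT array shares the spike-in profile of the BLJ arrays, so a batch seen in the spike-ins and genotype cannot be told apart here.

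Cells sorted by the cortex marker CO2 were compared with those sorted by the ground tissue marker J0571 in WT, a contrast in which ecotype differs as well. Root zone is labelled for the CO2 cells alone, so it cannot be matched. The control probes differed too, with a GAPDH 3' to 5' ratio of 2.83 ± 0.36 on the CO2 arrays and 0.27 ± 0.19 on the J0571 WT arrays, and an actin ratio of 3.05 ± 0.35 against -0.35 ± 0.59. AT2G25450 was highest in CO2 cells (6025 ± 1430 against 11.3 ± 7.12, 7.79 ± 0.26, adjusted p = 5.97e-07), then AT4G15390 (5.51 ± 0.18), the subtilase gene SBT4.12 (5.00 ± 0.23), AT3G53980 (4.65 ± 0.26), AT1G69080 (4.47 ± 0.22) and AT3G18280 (4.42 ± 0.25). AT5G45210 (-5.45 ± 0.22), AT2G14900 (-5.39 ± 0.27), AT4G29200 (-5.33 ± 0.18), ccb382 (-5.06 ± 0.17), the plastid ribosomal protein gene rpl14 (-4.89 ± 0.17) and AT4G11290 (-4.84 ± 0.28) were lowest. Endodermis genes were lower in CO2 cells, 4 of 4 also over the list alone: DIR9 (-3.495 ± 0.36, 244 ± 149 against 2688 ± 616), SGN1 (-3.18 ± 0.34), GSO1 (-2.85 ± 0.23) and EN7 (-1.25 ± 0.20), with the set moved down (adjusted p = 0.01, and adjusted p = 0.183 with an estimated correlation). Auxin response genes were higher, 6 of 6 in both counts, among them GH3.3 (4.34 ± 0.32), LBD16 (3.92 ± 0.32), IAA29 (3.35 ± 0.27) and WES1 (2.49 ± 0.22, set adjusted p = 0.000101, and adjusted p = 0.183 with an estimated correlation). Of 5 cortex genes AT1G62510 (3.97 ± 0.17) and NPF6.4 (1.31 ± 0.21) rose and 3 fell, CO2 itself (-1.74 ± 0.55), CORTEX (-1.17 ± 0.30) and AT5G02000 (-0.88 ± 0.18) (adjusted p = 0.62, median -0.88 but mean 0.30). In the BIRD family, BLJ (-2.94), BIB (-1.56) and JKD (-0.59) were lower, 3 of 3 measured (set adjusted p = 0.057), JKD being lost without WT 2_1 (adjusted p = 0.0691), WT 2_2 (0.089), CO2 1 (0.0537) or CO2 3 (0.0745) and after quantile normalization (0.123). All 3 gibberellin genes rose (adjusted p = 0.0996), and 1 of 3 wound genes did (0 over the list alone, adjusted p = 0.59). Calls numbered 8226 of 14357 (3334 up, 4892 down), with 3812 up and 3967 down after quantile normalization.

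Against WT meristems of the same ecotype, CO2 cells had higher cortex genes, 4 of 5 in both counts: AT1G62510 (5.20 ± 0.21, 656.7 ± 23.2 against 2.31 ± 0.68), NPF6.4 (4.76 ± 0.26), CORTEX (3.04 ± 0.47) and AT5G02000 (2.47 ± 0.24, set adjusted p = 0.0174, and adjusted p = 0.298 with an estimated correlation). The fifth, CO2, the gene that the sort marker is named after, read -0.71 ± 0.63 (79.1 against 107.7, adjusted p = 0.331). It was called lower than in J0571 cells, so its transcript does not bear out the label. CO2 cells stands for the cells so labelled throughout. Of 7 auxin response genes 6 rose and 1 fell in both counts, with GH3.3 (7.24 ± 0.36), LBD16 (5.93 ± 0.34), IAA29 (3.21 ± 0.32) and LBD29 (2.11 ± 0.27) first (adjusted p = 0.0174, and adjusted p = 0.298 with an estimated correlation). The 3 gibberellin receptor genes rose, GID1B by 3.38 ± 0.23, GID1A by 1.91 ± 0.27 and GID1C by 1.37 ± 0.33 (adjusted p = 0.00543, but 0.0715 without meristem WT 1), and STZ (4.89 ± 0.22) and CML38 (4.10 ± 0.23) rose of 3 wound genes. Both sets moved up (adjusted p = 0.0388 each, and adjusted p = 0.298 each with an estimated correlation). DIR9 (3.05 ± 0.44), SGN1 (2.68 ± 0.40) and GSO1 (2.60 ± 0.26) rose and EN7 (-0.87, adjusted p = 0.0074, but 0.0827 without meristem WT 1) fell, with the set not called (adjusted p = 0.113). Calls numbered 11113 of 15321 (4776 up, 6337 down). Per the labels both groups come from the meristematic zone, the CO2 cells by sorting and the meristems by dissection, so cell type and handling differ together.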

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

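The tests of epidermal markers and of lines within an array profile were chosen after the results were seen. The other tests and the splits of the samples were set before their results were seen, except that for the spike-in test AT3G28550 had been seen before.

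WT against SHR differed between the two-cycle and one-cycle arrays in 5697 probe sets. Of 100 splits drawn, 1 (the real one) gave as many, and the highest of the others gave 2687. The splits mixed WT and SHR within each protocol, so the difference between them entered the spread and could lower the other counts. They therefore cannot exclude chance for the interaction. Scaling of the arrays is argued against, since 5470 were called after quantile normalization, 4954 of them among the 5697 in the same direction, although the split turned from 3210 positive and 2487 negative to 2694 and 2776. A 3' bias of the two-cycle SHR arrays, whose GAPDH 3' to 5' ratio was 2.458 (log2) against -0.015 in two-cycle WT, stays open. Within the meristem BLJ arrays, those of high 3' bias differed from the other by -0.291 (bootstrap -0.358 to -0.242) between probe sets of positive and of negative interaction, which lies between the bounds of -0.5 and -0.1 set beforehand. Here the bootstrap resampled probe sets, and the contrast rests on 2 arrays against 1, so its range does not measure the spread between arrays. A biological difference between the sample sets, which the labels do not describe, was not tested.

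The 6 UAS lines differed in 10456 probe sets by an F test. Of 100 splits drawn, 1 (the real one) gave as many, with 3595 the highest of the others, so a chance division of these arrays is unlikely. The arrays labelled UAS-JKD and UAS-SCR stood apart in their control probes, outside the main measurement. Their GAPDH ratios were 1.215 and 1.399 against -0.05 in SHR, and their spike-in ratios -7.657 and -7.848 against -5.351. In meristem BLJ these were 7.087 and -7.851 against 3.476 and -4.915 in meristem WT.

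The lines labelled UAS-JKD and UAS-SCR shared much of their change against SHR. An array batch seen in the spike-in controls may account for it, because meristem BLJ, which has the same spike-in profile, differed from WT by a median of 0.923 over the probe sets raised in both lines and -1.194 over those lowered, a difference of 2.117 (bootstrap 1.989 to 2.298). The bootstrap resampled probe sets, which are not independent, and its range does not measure the spread between arrays. Outside that profile, UAS-NUC gave 2.118 over the same probe sets, UAS-IME 1.333, UAS-BLJ 0.646 and UAS-MGP 0.553, but these share the SHR arrays on which the probe sets were chosen, and no value without change was computed for them. Epidermal cells in the sort may account for part of it as well, since the epidermis and root hair markers were raised by a median of at least 1.529 in both lines (and by 1.009 in UAS-NUC), though sorting by J0571 fluorescence should remove such cells and 5 of the 6 measured markers read above 30 in SHR (GH9C1 read 29.2). The design confounds the batch with these lines, and an effect shared by JKD and SCR stays open.

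In the 3 against 3 comparisons, 10 splits are possible, so no share under 0.05 can be had. For WT against SHR (5445 one-cycle, 4122 two-cycle), UAS-BLJ (1756), UAS-MGP (1431), the line labelled UAS-JKD (7287), UAS-SCR (7524) and UAS-IME (3333) against SHR, and CO2 against J0571 cells (8226), 1 of 10 splits gave as many and the others at most 0 by limma, with 6 to 2498 probe sets at an unadjusted p under 0.05. Against WT, 1 of 10 did so for each line, with at most 2 in another split (250 to 5312 at an unadjusted p under 0.05). For UAS-NUC against SHR (6423), 1 of 10 did, with 1597 in another. Between the lines, 1 of 10 did for 12 pairs, with 887 in another split for UAS-NUC with the line labelled UAS-JKD (2169) and at most 5 for the rest (142 to 4652 at an unadjusted p under 0.05), and 2 of 10 for UAS-NUC with UAS-MGP (4645, another 5344), UAS-SCR (2405, another 3871) and UAS-IME (1274, another 3645), where UAS-NUC 2 stood on the other side. That array correlated more closely with another group (0.972) than with its own (0.959). So did UAS-SCR 3 (0.961 against 0.946), meristem BLJ 1 (0.898 against 0.876) and WT two-cycle 2 (0.946 against 0.942). With only the array in question left out, counts were 8467 for UAS-NUC against SHR, 4503 for UAS-SCR against SHR, 2425 for meristem BLJ against WT and 3959 for two-cycle WT against SHR.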

How the results depend on the processing

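UAS-JKD stands here for the line labelled so, in which the JKD probe read lower than in SHR. Chosen after the data were seen were the alternatives for the UAS lines against WT and each other and for their shared response, the fits with 1 array left out for the protocol difference and the gene lists, the fit without BLJ arrays 2 and 3, the comparisons within an array profile, and the added lists. The others were set before the data were examined. Of the counts and scores, 347 values stayed within 1.5 times or kept their side, 39 moved and 7 reversed. Of the gene values 2172 kept their side, 77 lost and 15 gained a call and 10 reversed, and of the list values 246, 25, 13 and 5. With a 70th percentile filter, which tests fewer probe sets, 2640 were called in two-cycle WT against SHR, 1116 in UAS-BLJ, 4830 in UAS-JKD, 4771 in CO2 against J0571, 7264 in CO2 against meristem, 3475, 2468, 3314, 2988, 3635 and 2750 in UAS-BLJ, NUC, MGP, JKD, SCR and IME against WT, and 6802 in the F test. On the 6 arrays of the groups alone, 3456 were called in UAS-BLJ and 3494 in UAS-NUC. With the replicate number as a block, 2657 were called in two-cycle WT against SHR and 2849 in meristems (1431 up, 1418 down), where the numbers share no pairing. In UAS-IME, the block over all 24 arrays gave 3320 calls, 3209 of them among the 3333 without it in the same direction, and changed the call of no gene named for that line. It need not remove a pairing of UAS-IME and SHR alone. In meristem BLJ against WT, values as deposited gave 2140 calls, eBayes without trend 155, and BLJ arrays 2 and 3 left out 6483 (1 BLJ array, assumed to vary like WT).

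The signature from the one-cycle arrays gave 0.413, 1.796, 0.49, 1.456, 1.343 and 1.098 in UAS-BLJ, NUC, MGP, JKD, SCR and IME, opposite to the two-cycle signature. Of the list calls, 0 held with an estimated correlation and fry called 26. Beside the sets given in the Results, fry called further sets that camera did not. In CO2 against J0571 these were the BIRD family (fry adjusted p = 3.59e-06), cortex (0.00198) and gibberellin (0.00594). In UAS-NUC they were cortex (0.000168) and wound genes (0.00848), and in UAS-SCR endodermis (0.0118) and gibberellin (0.0218). The others were gibberellin in UAS-MGP (0.0478) and endodermis in CO2 against meristem (0.00956). BLJ in UAS-JKD vs SHR read 0.033 with pseudocount 64, and from -0.694 (without UAS-JKD 2) to 0.292 (without UAS-JKD 1). JKD in UAS-SCR vs SHR read from -0.391 (without UAS-SCR 1) to 0.092 (without UAS-SCR 3). JKD in meristem BLJ vs WT read 0.538 as deposited, 0.061 with pseudocount 64, and from -0.944 to 0.426 with 1 array left out. None of these passed the test. List medians with a changed test direction were 0.047 (wound_stress in UAS-MGP) and -0.052 (gibberellin in UAS-IME) after quantile normalization, and without a filter 0.162 (endodermis in UAS-NUC), 0.104 (gibberellin in UAS-IME) and 0.292 (auxin in meristems). The cause was not tested.

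With 1 array left out, counts ran from 2058 to 3959 in two-cycle WT against SHR (lowest without WT 1), from 3496 (without UAS-NUC 1) to 8467 (without UAS-NUC 2) in UAS-NUC, from 790 (without UAS-MGP 1) to 1066 in UAS-MGP, from 4503 (without UAS-SCR 3) to 7671 in UAS-SCR, from 1896 (without UAS-IME 1) to 2938 in UAS-IME, and from 0 by limma (without BLJ 2, with 2747 at an unadjusted p under 0.05) to 2425 (without BLJ 1) in meristems. The two-cycle signature in UAS-MGP ran from -0.248 to 0.05 (without UAS-MGP 2). Quantile normalization, or its absence in meristems, shifted the median of all probe sets by 0.485 in meristems, 0.156 in CO2 against J0571 and -0.145 in the protocol difference. The 10th percentile of the signal ran from 2.39 to 17.23 between arrays, which limits what can be said of dim probe sets.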

Other observations

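The gene lists and families below and the test on Columbia arrays were chosen after the annotation or the results were seen, and each second p in parentheses is the adjusted p with an estimated correlation. Plastid-encoded genes moved together in most comparisons. Of 69, 64 rose in UAS-SCR (adjusted p = 5.67e-27, and adjusted p = 0.163), 49 in the line labelled UAS-JKD (adjusted p = 3.38e-14, and adjusted p = 0.484), 39 in UAS-MGP (adjusted p = 6.03e-23, and adjusted p = 0.235), 39 in UAS-NUC (adjusted p = 5.56e-09, and adjusted p = 0.505), 38 in UAS-IME (adjusted p = 3.04e-16, and adjusted p = 0.538) and 10 in UAS-BLJ (adjusted p = 0.0322, and adjusted p = 0.695). In WT against SHR 29 rose in the one-cycle set (adjusted p = 6.03e-06, and adjusted p = 0.536) and 31 fell in the two-cycle set (adjusted p = 2.09e-08, and adjusted p = 0.559). In CO2 cells 56 of 64 were lower than in J0571 cells (adjusted p = 1.51e-11, and adjusted p = 0.642). Against meristems 66 of 67 were lower in CO2 cells (adjusted p = 4.13e-11, and adjusted p = 0.616), and in meristem BLJ the list moved up with 1 gene called (adjusted p = 2.99e-13, and adjusted p = 0.741). Set against lines of the same array profile, the list was not called in UAS-NUC (10 fell, adjusted p = 0.21), UAS-MGP (5 rose, adjusted p = 0.992) or UAS-IME (5 rose, adjusted p = 0.581), but was higher in UAS-SCR than in the line labelled UAS-JKD (6 of 69 called, median 0.52, adjusted p = 1.27e-17, and adjusted p = 0.146).

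Genes of mitosis fell, 7 of 13 each, in UAS-NUC (adjusted p = 0.0204), the line labelled UAS-JKD (adjusted p = 0.014) and UAS-SCR (adjusted p = 0.0059), with adjusted p = 0.637, 0.567 and 0.6 with an estimated correlation. Genes of DNA replication and histones fell there too (6, 4 and 7 of 10, adjusted p = 0.018, 0.0303 and 0.00619, and 0.637, 0.567 and 0.6 with an estimated correlation). In WT of the two-cycle set the mitosis genes (3 of 11) and the DNA replication genes (5 of 10) rose (adjusted p = 0.0176 each, and adjusted p = 0.6 each). Neither list was called in WT of the one-cycle set. Both lists moved down in meristem BLJ with no gene called (adjusted p = 0.00287 and 0.00759, and adjusted p = 0.691 each) and in CO2 against J0571 cells (8 of 12 and 7 of 10, adjusted p = 0.0346 each, and adjusted p = 0.642 each). In CO2 cells, labelled as of the same root zone, all 13 mitosis genes were lower than in meristems (adjusted p = 0.000435, and adjusted p = 0.616 with an estimated correlation), as were 10 of 10 DNA replication and histone genes (adjusted p = 0.00739, and adjusted p = 0.616). Genes of endoplasmic reticulum bodies rose in UAS-NUC (4 of 6, adjusted p = 0.018, and adjusted p = 0.505) and the line labelled UAS-JKD (4 of 6, adjusted p = 0.0442, and adjusted p = 0.567) and fell in WT of the two-cycle set (5 of 6, adjusted p = 0.000848, and adjusted p = 0.549). In WT of the one-cycle set 3 of 6 rose, with a median of 1.14, and the set was not called (adjusted p = 0.113). Glycosyltransferases of the UGT family were lower in WT of the two-cycle set (16 of 32, adjusted p = 4.99e-06, and adjusted p = 0.549) and higher in CO2 than in J0571 cells (18 of 32, adjusted p = 9.17e-05, and adjusted p = 0.642). The list of vascular genes was called in no comparison by camera. In the lines labelled UAS-JKD and UAS-SCR, GH9C1 read 423.1 and 319.2 against 29.2 in SHR, EXPA7 400.9 and 259 against 42.5, and CSLD2 1359 and 1173 against 408.1.

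Some probe sets were on in either SHR or the group set against it and near the floor in the other, 34 in WT, 13 in UAS-IME, 12 in the line labelled UAS-JKD, 9 in UAS-BLJ, 8 in UAS-SCR, 5 in UAS-NUC and 1 in UAS-MGP. A strain or seed stock variant might place such loci side by side, and of 38 loci, 5.3% had another within 20 genes, where 10000 random sets of the 8470 tested loci had a median of 5.3% and a 95th percentile of 15.8% (permutation p = 0.66), but the loci of a variant need not be neighbours, so this excludes none. In arrays of the Columbia ecotype, 22 of the 34 probe sets of WT against SHR (64.7%, exact 95% binomial interval 46.5 to 80.3) lay nearer to SHR than to WT of the C24 ecotype in both CO2 cells and WT meristems, against 540 of 1987 other probe sets called with at least 2-fold change (27.2%). Columbia alleles in the SHR line may account for part of these differences, a hypothesis found and tested on the same data, in which the other probe sets were not matched for the size of their change. The cell types of the Columbia arrays differ too, a root zone is labelled for these arrays alone, and an effect of SHR itself stays open.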
